A study of Homo sapiens with 12 samples.

How the data were processed

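Total RNA from 12 separate cultures of HMT-3522 S1 cells was labelled with biotin and measured on Affymetrix human expression arrays, 1 array per culture. The 4 groups of 3 cultures were 2D control, 2D TRAIL, 3D control and 3D TRAIL, as the sample labels and the series design give them. The treatment text is the same for all 12 samples: caspase inhibitors at 1 µM each for at least 2 hours before TRAIL at 1 µg/ml for 8 hours. It does not say whether the vehicle cultures also received the inhibitors, so each TRAIL comparison is read as TRAIL treatment as labelled, with the inhibitors on at least the TRAIL side.

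The deposited values are intensities on a linear scale for 22283 probe sets per array. Per the labels the authors used GCRMA and Partek 6.2, but the deposited intensities do not have the properties of GCRMA values. They are not in log2, their quantiles differ between arrays, and their 2% trimmed mean is the same on every array (150.06 to 150.08), as a scaling of each array to a common target gives. The values were therefore used as scaled linear intensities; log2 was taken and no further normalization was applied. No detection calls were used. The median signal per array was 38.8 to 53.1, and the number of arrays, 3 per group, limits the precision of every comparison.

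Of the 22215 probe sets that are not array controls, 19065 map to 1 gene symbol in the probe table of the platform, 1043 map to several and 2107 have no entry. The gene numbers of 19053 of the single-symbol probe sets matched the RefSeq gene table, and 0 symbols changed by it. Each of the 11963 genes was represented by its probe set with the highest mean over the 12 arrays. A gene was tested if its value lay above the median of its array on at least 3 of the 12 arrays, which kept 7828 genes and left out 4135 as dim. Where a gene was at or below the array median on all 3 arrays of the lower group, or in its mean, its fold change is given against that median as "at least".

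The model was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 1 mean per group and all 12 arrays in the fit. The contrasts were TRAIL minus control in 2D, TRAIL minus control in 3D, the difference between these responses (3D minus 2D), 3D minus 2D in control cultures, and 3D minus 2D in TRAIL cultures. P-values were two-sided and Benjamini-Hochberg adjusted per contrast, with a threshold of 0.05. A gene is called when it passes this threshold. Errors beside log2 changes are standard errors from limma, with n = 3 cultures per group. They rest on 1 estimate of the spread per gene over all 4 groups, so they do not show where a group varied more. Errors beside group means are SDs. The replicate numbers were not treated as pairs, since the design text describes separate cultures. The responses in 2D and 3D share no array, so their correlation across genes is not forced by a shared control; genes are not independent replicates, and no p is given for it.

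Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 29 lists per contrast. Camera with an estimated correlation and fry (statmod 1.5.0 installed) were run beside it. Fry tests whether the genes of a list move on balance in 1 direction and compares them with no other genes. The lists cover the TRAIL death receptor pathway, pro-survival and pro-death BCL2 family genes, NF-kB targets, interferon-stimulated genes, AP-1 and immediate early genes, the unfolded protein and amino acid stress response, cytosolic heat shock genes, p53 targets, cell cycle genes, cholesterol synthesis, fatty acid synthesis, glycolysis and hypoxia, oxidative phosphorylation, cytosolic ribosomal proteins, hemidesmosome and basement membrane, epithelial junctions and polarity, mesenchymal and matrix remodelling genes, keratinocyte differentiation, luminal markers, basal and myoepithelial markers, milk and secretory genes, EGF receptor ligands and feedback genes, autophagy and lysosome genes, chromatin architecture genes, and markers of fibroblasts, leukocytes, endothelium and adipocytes. They hold 581 genes, of which 512 have a value and 398 were tested; a gene may stand on more than 1 list.

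The groups, contrasts, test, lists and the rule for named genes were fixed before the data were examined. The rule takes, per contrast, the 10 highest and 10 lowest log2 changes among called genes whose replicate values do not overlap between the groups (for the difference, called genes). It adds TNFRSF10B, CASP8, CFLAR, FADD, NFKBIA, TNFAIP3, CXCL8, MKI67 and ITGB4 whatever their values, and up to 4 called members of each list, or up to 2 members as values where none is called. The rule also names TNFRSF10A, TNFRSF10C, TNFRSF10D, TNFRSF11B, TNFSF10 and BIRC3. These were not tested, because they were dim or had no probe set with 1 symbol.

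The alternatives fixed with the design were no filter and a stricter filter on dim genes, the mean of the probe sets of a gene, each probe set on its own, quantile normalization, a shift of each array to the same median, eBayes without the trend or with robust estimation, array weights, weights per group, a fit of the compared arrays alone, a block for the replicate number, a fold threshold, and leaving out each array in turn. Added after seeing the data were an offset of 16 or a floor of 32 before log2, the actin 3'/5' ratio or the 18S rRNA signal as a covariate, fits without 2D TRAIL 2 and 3 or without 3D control 1 and 3D TRAIL 1, and the gene lists with each array left out. Where such a fit leaves a group with 1 array, that array is assumed to vary like those of the other groups. The pipeline was tested on simulated data with 200 changed genes among 7828, in 5 simulations per contrast. For the TRAIL contrast in 2D it recovered 43.2% of genes changed by 1 on the log2 scale and 79.6% of those changed by 2. For TRAIL in 3D the shares were 41.6% and 79.6%, and for the difference 17.2% and 58.4%. For 3D against 2D they were 39.2% and 81.6% in control, and 35.2% and 82.8% with TRAIL. False calls were 4.1% to 5.6% of calls. The simulated arrays had the same spread per gene in every group and no structure beyond the groups. The 3D arrays do have such a structure, described below, so these shares may not hold for the contrasts that use them. In 20 simulations camera called a list of genes raised in 2D TRAIL each time, and 1 of 560 unshifted lists. Each simulated gene varied independently, so these runs do not give the rate of false calls for lists whose genes vary together. In the data the estimated correlation was 0.141 for the NF-kB list, 0.25 for the cell cycle list and -0.025 for the interferon list.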

Results

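Gene expression was measured in HMT-3522 S1 cells, a line of non-malignant human breast epithelial cells, grown either as monolayers (2D) or embedded for 12 days in reconstituted basement membrane (3D), where they form acini. Cultures of each kind received vehicle (control) or the death ligand TRAIL at 1 µg/ml for 8 hours, with 3 separate cultures and 3 arrays in each of the 4 groups. Caspase inhibitors preceded TRAIL, and whether the vehicle cultures received them too is not stated. The layout asks how these cells respond to TRAIL in each kind of culture, and how the cultures differ. Values are array signals on the log2 scale, and the median signal per array was 38.8 to 53.1 on the linear scale. The first principal component held 41.1% of the variance and separated the 6 arrays from 2D cultures from the 6 from 3D cultures. Within a group, arrays correlated at r = 0.894 to 0.944 across genes. In 3D, some pairs of a control and a TRAIL array correlated as highly. These were 3D control 1 with 3D TRAIL 3 (0.9369) and 3D control 2 with 3D TRAIL 1 (0.9355). With its own replicates, 3D TRAIL 1 correlated at 0.8935 and 0.8957.

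The 2D TRAIL arrays 2 and 3 stood apart in their RNA controls. Their 18S ribosomal RNA control probe set read 11.53 and 11.45 (log2), against 3.52 to 6.89 on the other 10 arrays. Their actin 3'/5' log2 ratios were 1.41 and 1.33, with 1.01 on 3D control 3 as the next highest, and their GAPDH ratios were 0.59 and 0.70, with 0.32 as the next highest. By group, the actin ratio was 0.37 ± 0.22 (SD, n = 3) in 2D control, 1.02 ± 0.61 in 2D TRAIL, 0.31 ± 0.60 in 3D control and 0.07 ± 0.08 in 3D TRAIL.

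**Figure D1:**
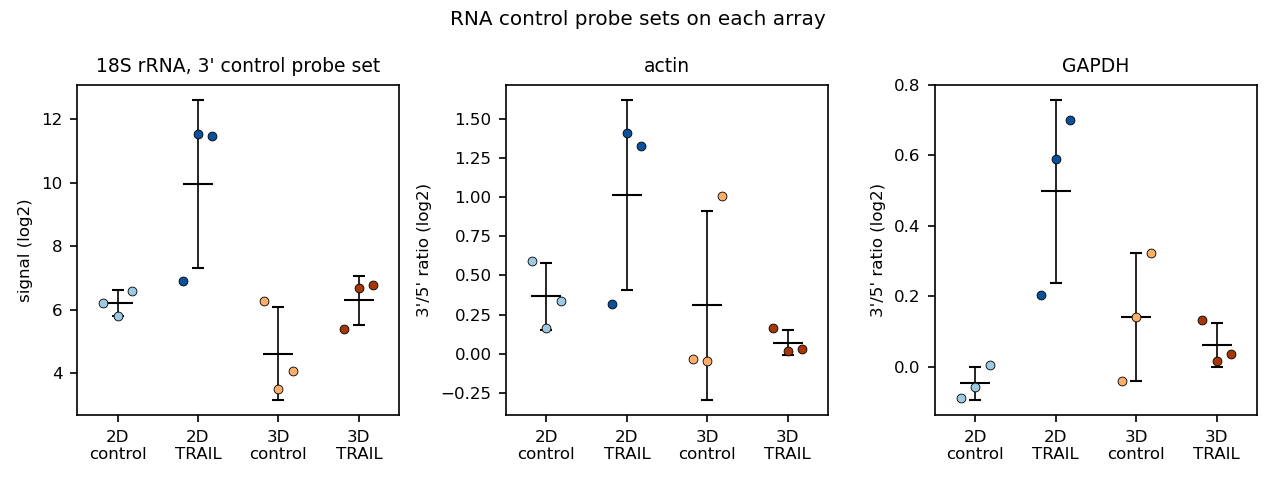
RNA control probe sets on each of the 12 arrays by group (x axis): 18S rRNA signal (log2, left panel) and the 3'/5' log2 ratios of actin and GAPDH (other panels), each on its own y scale. Points are arrays, lines and bars are the mean and SD of 3 arrays; 2D TRAIL 2 and 3 read 11.53 and 11.45 for 18S rRNA and lie above the other 10 arrays in all 3 panels.

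In monolayers, TRAIL raised a set of inflammatory and early response genes by large factors. The chemokine genes CXCL8 and CXCL2, which attract neutrophils, rose at least 20.9-fold (log2 change 5.90 ± 0.46, adjusted p = 1.02e-06) and at least 43.2-fold (7.57 ± 0.83, adjusted p = 3.21e-05). TNFAIP3, which encodes the NF-kB feedback inhibitor A20, rose 42.6-fold (5.41 ± 0.49, adjusted p = 3.79e-06), and IRF1, a transcription factor of the interferon system, rose 22.3-fold (4.48 ± 0.34, adjusted p = 7.44e-07). In each of these 4 genes, all 3 TRAIL cultures lay above all 3 control cultures, which the rule for naming the highest changes requires. Of 7828 genes, 125 were called, 106 higher and 19 lower, and 104 of them changed at least 2-fold.

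NF-kB target genes rose as a group. Of 23 tested members 14 rose and 0 fell, or 19 and 0 adjusted over the list alone (camera adjusted p = 8.48e-30, and adjusted p = 0.00624 with an estimated correlation). Beside the genes above, CXCL3 rose at least 7.02-fold, CXCL1 at least 3.55-fold, CCL20 at least 4.81-fold, and NFKBIA, the gene of the inhibitor IkB alpha, 4.72-fold (log2 change 2.24 ± 0.19, adjusted p = 2.55e-06). AP-1 and immediate early genes also rose, 8 of 17 tested, or 13 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.47e-15, and adjusted p = 0.0113 with an estimated correlation). Among them ATF3 rose at least 8.6-fold, FOS 7.73-fold, ZFP36 4.56-fold and KLF4 3.56-fold. Of the 17 tested mesenchymal and matrix remodelling genes 2 rose, the protease gene PLAU 11.2-fold (3.48 ± 0.31, adjusted p = 3.24e-06) and TWIST1 1.95-fold, with 5 higher adjusted over the list alone (camera adjusted p = 4.63e-05, and adjusted p = 0.0535 with an estimated correlation).

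Interferon-stimulated and p53 target genes shifted upward as lists with few called members. Of 16 tested interferon-stimulated genes 0 were called and 1 rose adjusted over the list alone (camera adjusted p = 0.00211, and adjusted p = 0.0437 with an estimated correlation). The largest log2 changes were 1.62 for IFI6, below the array median in both groups, and 1.53 for CXCL10, below it in 2D control. Of 17 tested p53 targets, PLK3 rose at least 2.22-fold, and 5 rose adjusted over the list alone (camera adjusted p = 0.00245, and adjusted p = 0.0437 with an estimated correlation). Cell cycle genes shifted downward, with 38 of 39 below 0 and a median log2 change of -0.63. AURKA (-1.24 ± 0.27) and CCNA2 (-1.10 ± 0.27) were called, and 5 fell adjusted over the list alone (camera adjusted p = 2.01e-13, and adjusted p = 0.0864 with an estimated correlation). The EGF receptor feedback list, with IER3 higher (4.97-fold) and EGFR lower (-0.97 ± 0.23) of 17 tested, had 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00511, and adjusted p = 0.196 with an estimated correlation). The 15 tested ribosomal protein genes were all above 0 by a median of 0.31. Of these 0 were called and 8 were higher adjusted over the list alone (camera adjusted p = 1.19e-06, and adjusted p = 0.0804 with an estimated correlation). After quantile normalization their mean change was 0 and the direction reversed (adjusted p = 0.947). Of 8 tested fatty acid synthesis genes SCD fell (-0.90 ± 0.21), with 3 lower adjusted over the list alone (camera adjusted p = 0.0135, and adjusted p = 0.0804 with an estimated correlation). Of 13 tested cholesterol synthesis genes 0 were called and 1 was lower adjusted over the list alone (camera adjusted p = 0.0458, and adjusted p = 0.196 with an estimated correlation).

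The remaining 19 lists were not called in 2D by camera. Fry called 12 lists in 2D, among them 3 of these 19, the death receptor pathway (adjusted p = 0.0163), the stress response (0.00707) and the luminal markers (0.00612). None of the 13 tested genes of the TRAIL death receptor pathway passed, over all genes or adjusted over the list alone (camera adjusted p = 0.0713). The log2 change was 0.63 ± 0.20 for TNFRSF10B, which encodes the receptor DR5 (adjusted p = 0.141), 0.55 for CASP9, 0.46 for CFLAR, 0.29 for CASP8 and 0.13 for FADD. Of 8 pro-death BCL2 family genes PMAIP1, which encodes NOXA, rose 7.65-fold (2.94 ± 0.38, adjusted p = 0.000219; list adjusted p = 0.482). Of 3 pro-survival members 0 were called (list adjusted p = 0.781), with MCL1 at 0.40. Of 21 stress response genes 3 rose, PPP1R15A 6.14-fold, XBP1 3.83-fold and CEBPB 1.71-fold (list adjusted p = 0.278). XBP1 was also the 1 called gene of 9 luminal markers (list adjusted p = 0.132). Single members were called in lists that were not. SQSTM1 rose 2.17-fold among 18 autophagy genes (list adjusted p = 0.87), ADM 2.58-fold among 20 glycolysis and hypoxia genes (0.948). PLEC fell among 18 hemidesmosome and basement membrane genes (-1.11 ± 0.24; list adjusted p = 0.728) and EGFR among 9 basal markers (list adjusted p = 0.948). No member was called among 11 heat shock genes (list adjusted p = 0.87), 20 oxidative phosphorylation genes (0.586), 22 junction genes (0.377), 13 keratinocyte differentiation genes (0.0899), 7 milk and secretory genes (0.0713) or 21 chromatin architecture genes (0.948). The median and mean of the list differed in sign for heat shock (0.07 and -0.05), glycolysis (-0.02 and 0.08), hemidesmosome (0.01 and -0.06), autophagy (-0.12 and 0.05) and chromatin genes (-0.03 and 0.03). For the junction list the median was 0.00 and the mean -0.09, and for the fibroblast list 0.10 and 0.00 with a test pointing down. Markers of fibroblasts, leukocytes, endothelium and adipocytes, 2 or 3 tested genes each, had 0 called members and adjusted p of 0.87 to 0.948. The proliferation marker MKI67 changed by -0.73 (adjusted p = 0.229) and ITGB4 by 0.10.

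Outside the lists, the activin subunit gene INHBA rose 16.9-fold and BHLHE41 at least 3.45-fold. The called genes with the lowest changes were RAPGEFL1 (-2.29 ± 0.49, at least 1.15-fold), DDX46 (-1.52), DKK1, a Wnt inhibitor (-1.46 ± 0.17, adjusted p = 8.13e-05), SMC3 (-1.46), RMI1 (-1.45), EPRS1 (-1.38), DEK (-1.29), SSX2IP (-1.27), AURKA (-1.24) and NUP188 (-1.13). Of the 38 called genes that the rule names, 17 kept the call whichever of the 6 arrays was left out. These were DKK1 and 16 higher genes, CXCL2, CXCL8, CXCL3, TNFAIP3, IRF1, ATF3, NFKBIA, PMAIP1, FOS, ZFP36, KLF4, PPP1R15A, XBP1, PLAU, IER3 and SQSTM1. Leaving out 2D control 1, 2 or 3 ended 18, 12 and 16 of the 38 calls, and leaving out 2D TRAIL 1, 2 or 3 ended 15, 15 and 19, with CCL20, INHBA, PLK3, CCNA2, DDX46 and SMC3 lost in every case. CCNA2, 1 of the 2 called cell cycle genes, was also lost without the dim filter, with the mean of probe sets and with a replicate block.

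The 125 genes came from limma, where 1143 genes had an unadjusted p under 0.05 and chance would give 391. The number was 67, 79, 66 and 54 without 2D control 1, 2D control 3, 2D TRAIL 2 and 2D TRAIL 3, and 36 without 2D TRAIL 2 and 3 together. Of the 36, 23 were among the 125. With the 18S signal as a covariate 4 lists were no longer called, while 3 of their mean changes moved little and the standard errors grew. The mean was 0.79 against 0.83 for interferon-stimulated genes (adjusted p = 0.0746; median standard error 0.77 against 0.53), -0.35 in both fits for fatty acid synthesis (0.126; 0.38 against 0.26) and 0.59 against 0.67 for EGF receptor feedback (0.102; 0.53 against 0.36). That of p53 targets fell from 0.60 to 0.36 (0.15; 0.33 against 0.27). The list calls ended for cholesterol synthesis without 2D control 1 (adjusted p = 0.154), 2D control 3 (0.105), 2D TRAIL 1 (0.21) or 2D TRAIL 2 (0.0605), and for fatty acid synthesis without 2D control 1 (0.0926). TRAIL pathway genes were called after quantile normalization (0.0405) and without 2D control 1 (0.0433) or 2D TRAIL 1 (0.0366), and milk genes without 2D control 3 (0.0267) or 2D TRAIL 2 (0.0223). Pro-death BCL2 family genes were called without 2D TRAIL 2 and 3 together (0.0336), and keratinocyte differentiation genes without the dim filter (0.0442). With the mean of probe sets, cholesterol synthesis (0.101) and EGF receptor feedback (0.0578) were not called, nor was cholesterol synthesis after quantile normalization (0.112).

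**Figure D2:**
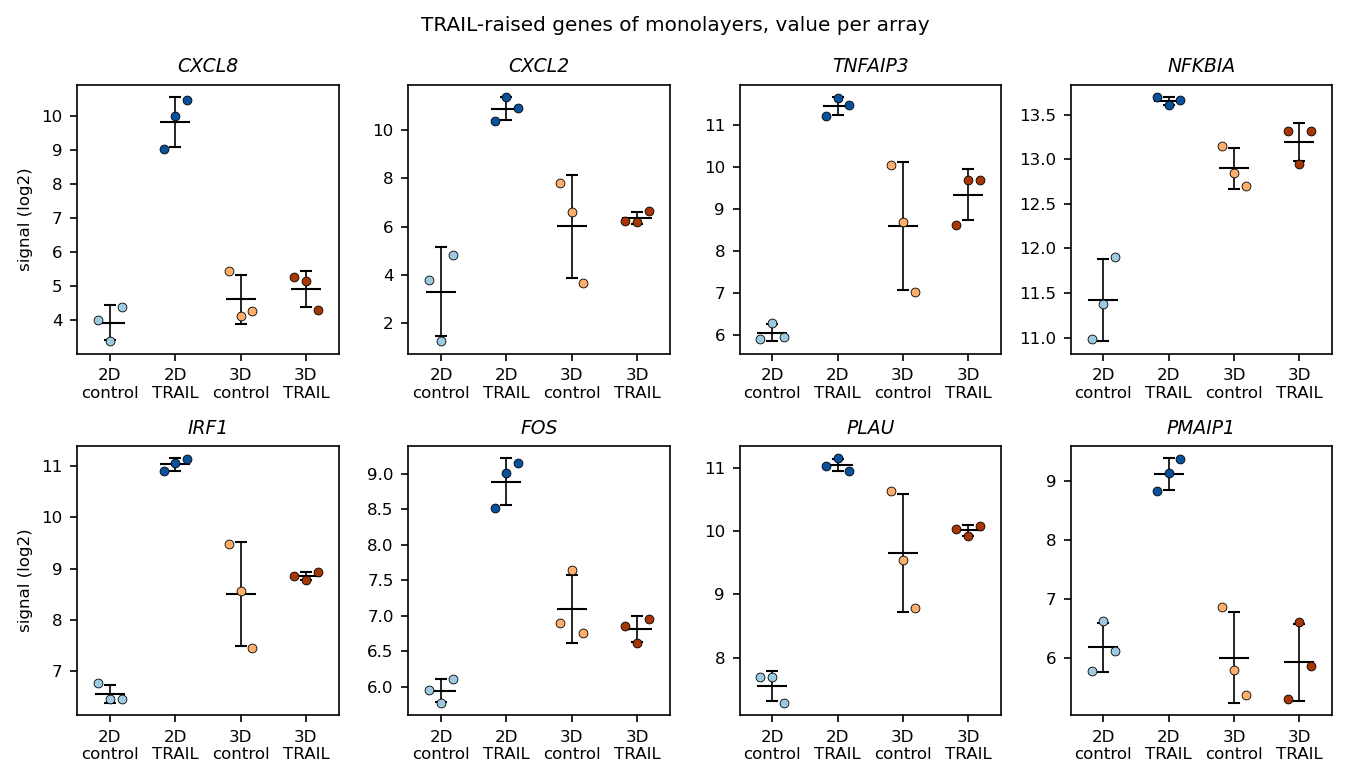
Signal (log2, y axis, a scale of its own in each panel) of 8 genes called higher with TRAIL in 2D, on each array of the 4 groups (x axis). Points are arrays, lines and bars are the mean and SD of 3 arrays; CXCL8 averaged 3.92 in 2D control, 9.82 in 2D TRAIL, 4.60 in 3D control and 4.91 in 3D TRAIL.

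In 3D cultures, no gene that TRAIL raised in monolayers was called with all arrays in the fit. CXCL8 changed by 0.30 ± 0.46 on the log2 scale (adjusted p = 0.997), NFKBIA by 0.30 ± 0.19 (adjusted p = 0.977) and TNFAIP3 by 0.75 ± 0.49 (adjusted p = 0.985). TNFAIP3 ranged from 7.02 to 10.06 in 3D control, and its standard error pools the spread of all groups. Its 3D change is therefore less certain than that error shows. The 106 genes raised in 2D had a median change of 0.01 in 3D, with 54 of them above 0, and the 19 lowered genes a median of 0.09, with 8 below 0. Over the 7828 genes the responses in 2D and 3D correlated at r = 0.036 (rho = 0.031) across genes, which are not independent replicates. In limma 0 genes passed, with a smallest adjusted p of 0.0684 for EXOC5. An unadjusted p under 0.05 was found for 429 genes, against 391 by chance. The 3D arrays did not group by treatment, however. Parted as 3D control 1, TRAIL 2 and TRAIL 3 against the other 3D arrays, they gave 657 genes. Such a structure adds to the spread within the labelled groups, so the count of 0 does not show that TRAIL changed no gene in 3D.

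The cell cycle list moved down in 3D as well. Of its 39 tested genes 37 lay below 0 with a median of -0.62. Over all genes 0 passed, and 9 were lower adjusted over the list alone (camera adjusted p = 2.86e-19, but adjusted p = 0.271 with an estimated correlation and 0.139 with fry). MKI67 stood at -0.22 ± 0.27. Of the largest fitted values, -1.55 for KIF23 rests on 3D groups that both lay below the array median. No detection calls were used, so its 3D signal was not shown to lie above background. The size of -1.38 for E2F1 rests on a 3D TRAIL mean below that median. Ribosomal protein genes, 15 of 15 above 0 with a median of 0.15, were the other called list, with 0 members called over all genes or adjusted over the list alone (camera adjusted p = 0.00132, but adjusted p = 0.443 with an estimated correlation). NF-kB targets had 0 of 23 called with a median of 0.20 (camera adjusted p = 0.808), and AP-1 genes 0 of 17 with a median of -0.05 (0.897). On the death receptor pathway list the changes were 0.18 for TNFRSF10B, -0.12 for CASP8, -0.03 for CFLAR and 0.11 for FADD. CASP10 changed by 1.83 ± 0.62 (adjusted p = 0.815), and its 3D control mean lay below the array median (at least 1.27-fold). ITGB4 changed by -0.14. After quantile normalization the ribosomal list was not called (adjusted p = 0.916), nor without the dim filter (0.103). Of the other 27 lists, 0 were called, and in 8 of them the median, mean and test differed in sign.

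The count of 0 became 6 without 3D control 1 (BBIP1, EXOC5, MBTPS2, PCM1, SLC30A1 and ZC2HC1A, all higher) and 1 without 3D TRAIL 1 (CDCA8, -2.16 ± 0.28). The ribosomal list was no longer called without either (adjusted p = 0.0544 and 0.097). EGF receptor feedback genes were called without 3D control 2 (0.0376), luminal markers with the actin covariate (0.029), and oxidative phosphorylation genes without 3D control 1 and 3D TRAIL 1 together (0.0357). EXOC5 alone passed in limma without the dim filter, with the mean of probe sets or without the trend. TCF4 passed beside it with each probe set on its own, and array weights gave 13 genes. The adjusted p of EXOC5 was 0.0398, 0.0238 and 0.00158 in the first 3 of these fits. Its means of 1.90 in 3D control and 5.40 in 3D TRAIL both lay below the array median, so its 3D signal was not shown to lie above background. Without 3D control 1 and 3D TRAIL 1 together 269 genes were called, and 3 of the 106 genes raised in 2D were among those higher, TNFAIP3 (1.84), INHBA (1.71) and RND3 (0.95). These 2 arrays were picked from the data, so those calls are circular. Of the genes called in these fits, RND3, BBIP1, SLC30A1, ZC2HC1A, CDCA8 and TCF4 were chosen after their values were seen.

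**Figure D3:**
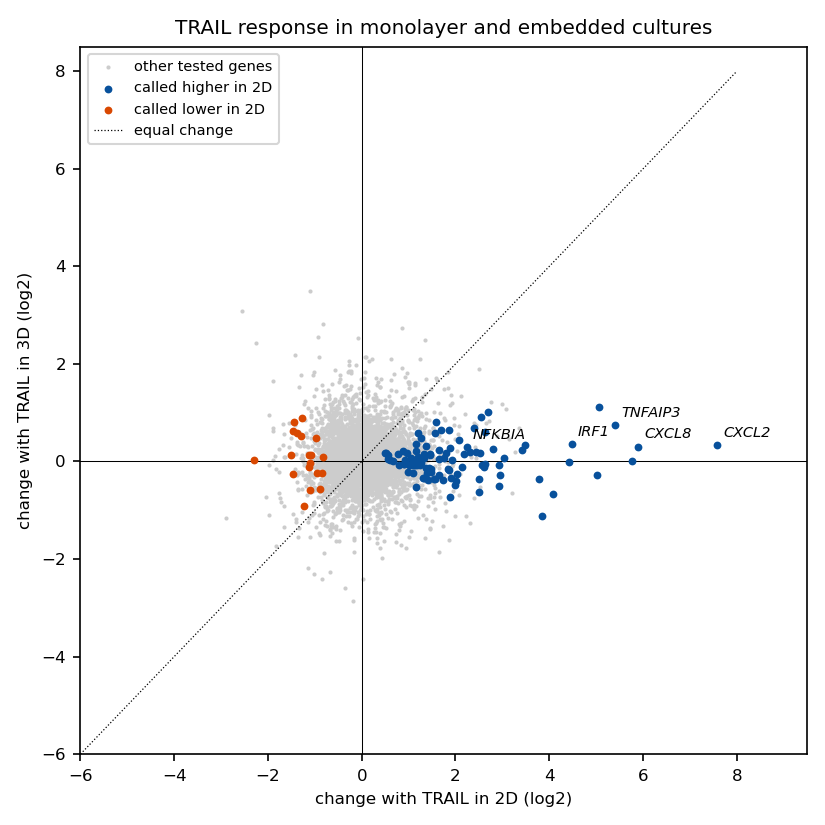
Change with TRAIL (log2) of each of the 7828 tested genes in 2D (x axis) and 3D (y axis), one point per gene, on equal scales. The 106 genes called higher in 2D spread along the x axis with a median of 1.56 in 2D and 0.01 in 3D.

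Whether the TRAIL response depends on the kind of culture was tested as the difference between the responses. A part of the NF-kB target and early response genes responded less to TRAIL in 3D than in 2D. The 3D minus 2D difference was -7.23 ± 1.18 on the log2 scale for CXCL2 (adjusted p = 0.00511) and -5.60 ± 0.66 for CXCL8 (adjusted p = 0.000231). It was -4.66 ± 0.70 for TNFAIP3 (adjusted p = 0.00234) and -4.12 ± 0.48 for IRF1 (adjusted p = 0.000231). The stress and early response genes ATF3 (-4.43 ± 0.58), FOS (-3.23 ± 0.37) and PPP1R15A (-2.74 ± 0.38) differed in the same direction, and so did the protease gene PLAU (-3.14 ± 0.44). In TNFAIP3, IRF1, FOS and PLAU all 3D controls read above all 2D controls, while CXCL2 and CXCL8 overlapped. TNFAIP3 read 7.02 to 10.06 in 3D control against 5.91 to 6.28 in 2D control. The differences of TNFAIP3, IRF1, FOS and PLAU therefore hold a higher 3D control level as well as a lower level with TRAIL in 3D. Of 7828 genes, 54 were called, 41 lower and 13 higher. The sizes for CXCL2, CXCL8 and ATF3 rest on 2D control means below the array median. With group means below it set to that median, the differences were -5.09, -4.23 and -3.12. The 2 groups of CXCL8 in 3D also lay below the median, so its 3D signal was not shown to lie above background.

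NF-kB target genes differed as a group, with 9 of 23 lower and 0 above 0, or 17 lower adjusted over the list alone, and a median of -2.53 (camera adjusted p = 1.02e-24, and adjusted p = 0.0118 with an estimated correlation). Beside those above, CXCL3 (-5.29, or -2.66 with means below the array median set to it) and NFKBIA (-1.94 ± 0.27, adjusted p = 0.00113) were called. NFKBIA read 12.7 to 13.15 in 3D control and 10.98 to 11.9 in 2D control, so its difference also holds a higher 3D control level. Of 17 AP-1 and immediate early genes 7 were lower, among them ZFP36 (-2.03) and KLF4 (-1.98), with 10 lower and 1 higher adjusted over the list alone (camera adjusted p = 4.58e-13, and adjusted p = 0.0198 with an estimated correlation). PLAU was the 1 called gene of 17 matrix remodelling genes, with 4 adjusted over the list alone (camera adjusted p = 0.00383, but adjusted p = 0.156 with an estimated correlation). XBP1 (-1.90 ± 0.35) was the 1 called of 9 luminal markers, also adjusted over the list alone (camera adjusted p = 0.00776, but adjusted p = 0.0904 with an estimated correlation). Of 16 interferon-stimulated genes 0 were called, over all genes or adjusted over the list alone (camera adjusted p = 0.0472, but adjusted p = 0.156 with an estimated correlation). Single called members of other lists were PMAIP1 (-3.02 ± 0.54), IER3 (-2.12 ± 0.45) and SQSTM1 (-1.20 ± 0.23). The cell cycle list showed no called difference (adjusted p = 0.749), with a median of -0.13 and a mean of 0.02. It is 1 of 9 lists, none of them called, in which the median, mean and test differed in sign.

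Outside the lists, GEM, a small GTPase gene, and IL1A, a cytokine gene, were lower by the difference (-4.13 ± 0.79 and -3.20 ± 0.71). Both rest on 2D control means below the array median, as does the 3D control mean of IL1A. With means below the median set to it, the difference of GEM was -3.50 and that of IL1A -2. The 10 highest called genes were EXOC5 (4.60 ± 0.79, adjusted p = 0.00852), MBTPS2 (3.61), PCM1 (2.86), ERBIN (2.45), RMI1 (2.25), SSX2IP (2.15), SMC3 (2.09), PKN2 (2.06), EPRS1 (1.96) and WASHC4 (1.82). EXOC5 lay below the array median in all but 2D control, and with means below it set to that median its difference was 1.18, that of MBTPS2 1.72 and that of PCM1 2.01. TNFRSF10B (-0.45), CASP8 (-0.41), CFLAR (-0.49), FADD (-0.03), MKI67 (0.51) and ITGB4 (-0.24) showed no called difference. Of 28 named calls 10 were kept whichever array was left out, those of CXCL2, CXCL8, TNFAIP3, ATF3, IRF1, FOS, PLAU, NFKBIA, KLF4 and PPP1R15A. None of the 10 positive calls was kept in that way. The call of EXOC5 was lost without 2D control 1, that of GEM without 2D TRAIL 2 or 3, and that of PMAIP1 without 2D TRAIL 3.

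The number of 54 became 28, 35 and 29 without 2D control 1, 2 and 3, 31 and 25 without 2D TRAIL 2 and 3. It was 105 without 3D TRAIL 1, and 30 and 33 without 3D TRAIL 2 and 3. Without 2D TRAIL 2 and 3 together, which leaves 1 array in that group, the calls were lost and all 54 genes kept their sign. The 54 were picked with all arrays in the fit, and the remaining arrays are the same. The kept signs are therefore no separate support. The interferon list was no longer called without 2D control 3 (adjusted p = 0.105), 2D TRAIL 2 (0.0712), 2D TRAIL 3 (0.0517), 3D control 1 (0.118), 3D TRAIL 1 (0.0892) or 3D TRAIL 3 (0.0981). Nor was it called without the dim filter (0.113), after quantile normalization (0.132), with the actin (0.123; mean -0.69 against -0.73) or 18S (0.119; -0.71) covariate, or without either pair of doubted arrays (0.17 and 0.182). Luminal markers were not called without 3D control 1 and 3D TRAIL 1 together (0.0644). Ribosomal genes were called without 2D control 3 (0.00742) and EGF receptor feedback genes without 3D control 3 (0.0297).

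**Figure D4:**
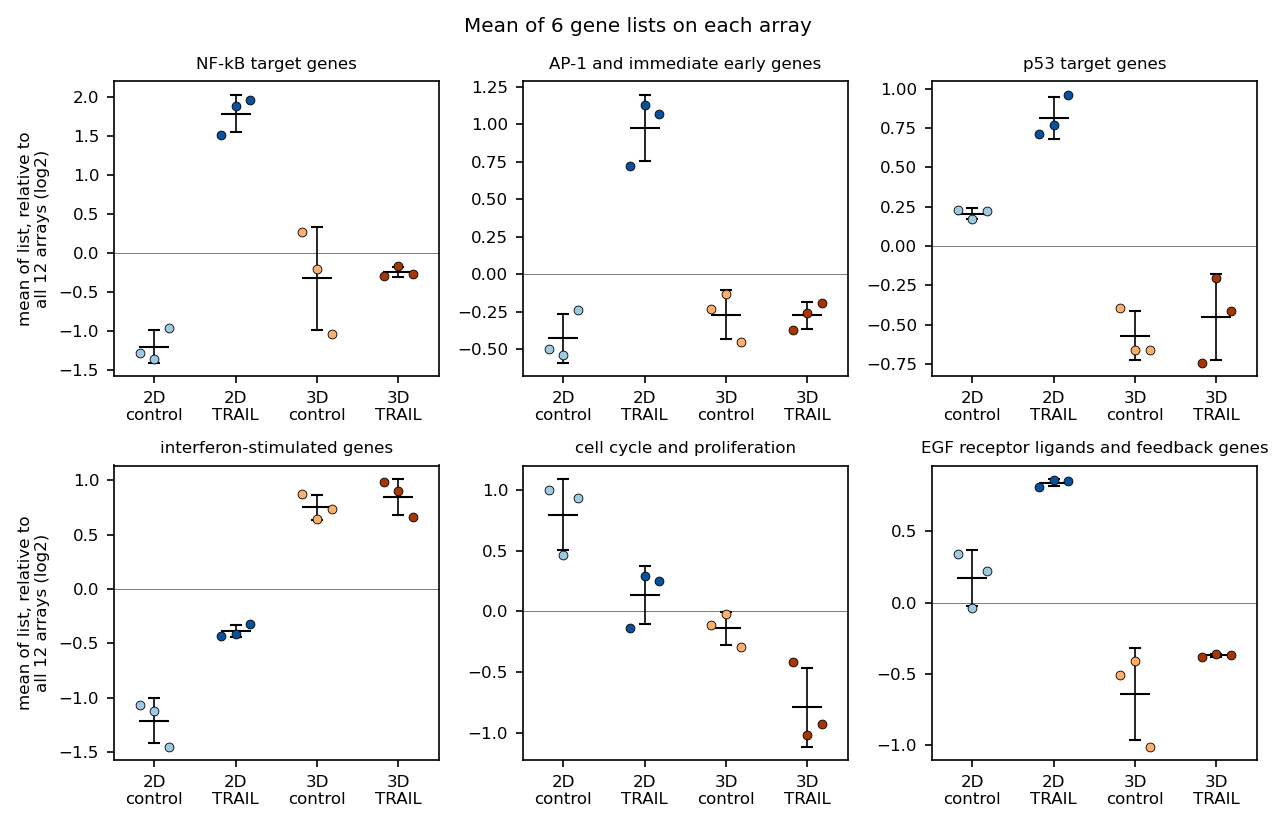
Mean signal of the tested genes of 6 lists on each array, relative to the mean over the 12 arrays (log2, y axis, its own scale in each panel), by group (x axis). Points are arrays, lines and bars are the mean and SD of 3 arrays; the NF-kB list lay at 1.51 to 1.96 in 2D TRAIL, -1.36 to -0.97 in 2D control and -1.04 to 0.26 in the 6 arrays from 3D cultures.

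In control cultures, cells in 3D expressed interferon-stimulated genes and some keratinocyte differentiation genes at higher levels, and some cell cycle genes at lower levels, than monolayers. Of the keratinocyte differentiation list, KLK5, a protease of the epidermis, was 20.1-fold higher (log2 change 4.33 ± 0.26, adjusted p = 1.31e-08). KRT16, a stress keratin of the same list, was 10.1-fold higher (3.33 ± 0.23, adjusted p = 4.21e-08). KRT15, a keratin of basal epithelial cells on the basal marker list, was at least 55.2-fold higher (5.95 ± 0.31, adjusted p = 4.26e-09). Camera did not call the basal marker list (adjusted p = 0.709). TOP2A, a topoisomerase of dividing cells, was 13.3-fold lower (-3.74 ± 0.42, adjusted p = 8.73e-06). TYMS, needed for thymidine synthesis, was 10.4-fold lower (-3.38 ± 0.26, adjusted p = 1.56e-07). Of 7828 genes, 2013 were called, 1023 higher and 990 lower in 3D, and 1238 of them differed at least 2-fold.

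**Figure D5:**
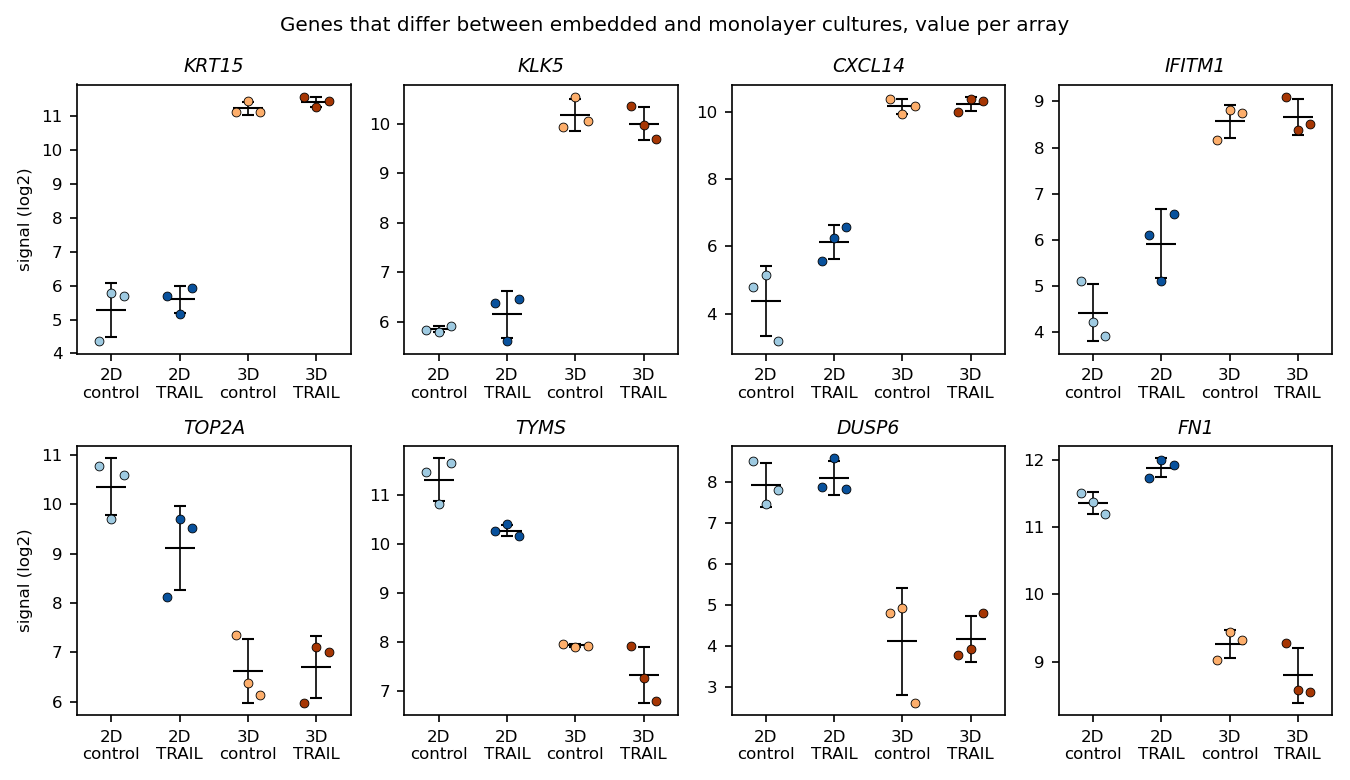
Signal (log2, y axis, its own scale in each panel) of genes called between 3D and 2D control cultures, on each array of the 4 groups (x axis). Points are arrays, lines and bars are the mean and SD of 3 arrays; KRT15 lay at 4.36 to 5.94 in the 6 arrays from 2D and 11.11 to 11.56 in the 6 from 3D, and TYMS at 10.16 to 11.65 and 6.80 to 7.97.

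Interferon-stimulated genes were the 1 list also called with an estimated correlation, 10 of 16 higher and 16 above 0, or 11 adjusted over the list alone (camera adjusted p = 4.52e-06, and adjusted p = 0.0143 with an estimated correlation). IFITM1 was at least 8.77-fold higher, ISG15 6.98-fold (2.80 ± 0.28, adjusted p = 2.55e-06) and IFIT1 at least 3.73-fold. Cell cycle genes were lower in 17 of 39 and higher in 2, or 22 and 2 adjusted over the list alone (camera adjusted p = 1.39e-05, but adjusted p = 0.545 with an estimated correlation). KIF11 was at least 5.31-fold lower, KIF23 at least 2.28-fold and MKI67 2.12-fold (-1.08 ± 0.27, adjusted p = 0.00792). Keratinocyte differentiation genes were higher in 5 of 13, or 7 adjusted over the list alone (camera adjusted p = 0.00051, but adjusted p = 0.0956 with an estimated correlation). Among them SPRR1B was at least 5.71-fold higher. Luminal markers were higher in 5 of 9, also adjusted over the list alone (camera adjusted p = 0.00948, but adjusted p = 0.0956 with an estimated correlation). Among them were EPCAM (at least 2.18-fold), CD24 (at least 2.73-fold), MUC1 (at least 1.8-fold) and KRT8 (2.01-fold).

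NF-kB target genes were higher in 7 and lower in 1 of 23, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.00948, but adjusted p = 0.547 with an estimated correlation). TNFAIP3 was 5.85-fold higher (2.55 ± 0.49, adjusted p = 0.0013), RELB at least 2.9-fold, IRF1 3.85-fold and NFKBIA 2.78-fold (1.48 ± 0.19, adjusted p = 4.02e-05), while CXCL8 differed by 0.68 (adjusted p = 0.295). TNFAIP3 varied between the 3D control cultures (8.60 ± 1.52, SD) more than between the 2D control cultures (6.05 ± 0.20), and without 3D control 1 the list was no longer called (adjusted p = 0.0942). p53 targets were lower in 5 of 17, or 8 adjusted over the list alone (camera adjusted p = 0.00948, but adjusted p = 0.0956 with an estimated correlation). Among them TIGAR was 9.04-fold lower (-3.18 ± 0.27). EGF receptor feedback genes were lower in 7 of 17, also adjusted over the list alone (camera adjusted p = 0.00718, but adjusted p = 0.369 with an estimated correlation). Among them DUSP6 was at least 5.77-fold lower, ETV5 at least 2.71-fold, SPRED2 2.26-fold and EGFR 2.18-fold.

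Other genes with the highest changes were SELENOP (at least 3.64-fold), CXCL14 (at least 26.5-fold), RBP4, USP2, S100P, CYP3A5 and CTSH (at least 16.1-fold). Those with the lowest were ASPM, a spindle gene (at least 4.31-fold lower), HELLS, AMIGO2 (at least 13.9-fold lower), SPDL1, EXOC5, FBN2 (at least 5.49-fold lower), ZFYVE16, LTN1, PCM1 (at least 8.56-fold lower) and ECT2. On the death receptor pathway list BIRC2 (-1.35 ± 0.30) and CYCS (-1.15 ± 0.22) were lower and CASP9 (0.94 ± 0.28) and DIABLO (0.60 ± 0.19) higher. TNFRSF10B (-0.19), CASP8 (-0.34), CFLAR (0.06), FADD (0.00) and ITGB4 (-0.19) showed no called change. Fry called 12 lists, among them 5 that camera did not, the glycolysis, oxidative phosphorylation, basal marker, autophagy and adipocyte lists (adjusted p = 0.00469 to 0.0169). Among the lists not called by camera, the median, mean and test differed in sign in 6. Of 108 named calls 83 were kept whichever array was left out. Leaving out 2D control 1, 2 or 3 ended 15, 14 and 17 of them, and leaving out 3D control 1, 2 or 3 ended 11, 18 and 15, with the calls of CXCL2, EPCAM, KIF23, HELLS, KLK7 and FAS among those lost, and that of MKI67 lost without 2D control 1. Without 3D control 2 the number of 2013 genes was 1337.

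With TRAIL present in both kinds of culture, some keratinocyte differentiation genes were again higher in 3D, and some NF-kB target genes were lower. KLK5 of the keratinocyte differentiation list was 14.4-fold higher in 3D (3.85 ± 0.26, adjusted p = 4.24e-08). KRT15, which stands on the basal marker list, was at least 56-fold higher (5.82 ± 0.31, adjusted p = 6.05e-09). CXCL8 was at least 19.4-fold lower (-4.92 ± 0.46, adjusted p = 2.39e-06), CXCL2 22.8-fold (-4.51 ± 0.83, adjusted p = 0.00149) and FN1, the fibronectin gene, 8.5-fold (-3.09 ± 0.20, adjusted p = 4.24e-08). Of 7828 genes, 1230 were called, 568 higher and 662 lower in 3D. The culture changes with and without TRAIL share no array and correlated across genes at r = 0.663 (rho = 0.644). Of the genes, 399 were higher in both (74.2 by chance), 412 lower in both (83.7 by chance) and 14 were called in opposite directions.

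NF-kB target genes were lower in 11 of 23, or 15 adjusted over the list alone (camera adjusted p = 3.27e-08, but adjusted p = 0.0764 with an estimated correlation). TNFAIP3, which was higher in 3D between controls, was 4.33-fold lower (-2.11 ± 0.49, adjusted p = 0.00836), while NFKBIA differed by -0.46 (adjusted p = 0.118). AP-1 and immediate early genes were lower in 13 and higher in 1 of 17, or 14 and 2 adjusted over the list alone (camera adjusted p = 3.27e-08, but adjusted p = 0.0526 with an estimated correlation). Among them ATF3 was 5.72-fold and FOS 4.24-fold lower. p53 targets were lower in 8 of 17, or 11 adjusted over the list alone (camera adjusted p = 1.99e-06, and adjusted p = 0.0159 with an estimated correlation). Among them were GDF15 (at least 3.25-fold), TIGAR (5.65-fold), the death receptor gene FAS (4.71-fold) and GADD45A (3.13-fold). Interferon-stimulated genes were higher in 7 of 16, also adjusted over the list alone (camera adjusted p = 2.84e-05, and adjusted p = 0.0173 with an estimated correlation). Among them IFITM1 was 6.68-fold and IRF9 4.13-fold higher. Cell cycle genes were lower in 12 of 39, or 15 adjusted over the list alone (camera adjusted p = 6.21e-07, but adjusted p = 0.257 with an estimated correlation). Among them TYMS was 7.7-fold and TOP2A 5.33-fold lower. Keratinocyte differentiation genes were higher in 4 of 13, or 6 adjusted over the list alone (camera adjusted p = 0.00391, but adjusted p = 0.153 with an estimated correlation). EGF receptor feedback genes were lower in 7 of 17, or 8 adjusted over the list alone (camera adjusted p = 3.12e-05, but adjusted p = 0.107 with an estimated correlation). Among them IER3 was 9.43-fold and SPRED2 4.28-fold lower.

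Among the genes of cell death, PMAIP1 was 9.1-fold lower in 3D with TRAIL (-3.19 ± 0.38, adjusted p = 2.48e-05), MCL1 was 2-fold lower and BAK1 higher (1.07 ± 0.34). TNFRSF10B was 1.56-fold lower (-0.64 ± 0.20, adjusted p = 0.0371), while CASP8 (-0.75, adjusted p = 0.0754), CFLAR (-0.44), FADD (-0.02), MKI67 (-0.57) and ITGB4 (-0.43) showed no called change. Other genes with the highest changes were SELENOP, RBP4, USP2, EPCAM, CSF1R, CXCL14 (17.3-fold), FABP4, CTSH (15-fold) and FZD10. Those with the lowest were PRR16, CCL20, AMIGO2 (at least 15.8-fold lower), KIF15, CXCL3, INHBA (at least 15.9-fold lower), HSD17B2 and GDF15. Fry called 16 lists, among them 9 that camera did not (adjusted p = 0.000672 to 0.0474), those of the death receptor pathway, stress response, fatty acid synthesis, glycolysis, matrix remodelling, basal markers, autophagy, fibroblasts and adipocytes. Camera called adipocyte markers with the actin covariate (0.0476) and basal markers with the 18S covariate (0.0344). Among the lists not called by camera, the median, mean and test differed in sign in 5. Of 87 named calls 62 were kept whichever array was left out. Leaving out 2D TRAIL 1, 2 or 3 ended 6, 19 and 16, and leaving out 3D TRAIL 1, 2 or 3 ended 11, 3 and 6, with TNFRSF10B, MCL1, BAK1, CCL20, EPCAM and KIF23 among those lost. The number of 1230 genes was 646 and 719 without 2D TRAIL 2 and 2D TRAIL 3, the arrays with the high 18S signal, and 228 without both.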

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

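The tests of exchanged labels, RNA quality, rRNA signal, the level of the 3D controls and the splits of the arrays for the TRAIL gene counts in 2D and in 3D were chosen only after the results were seen. The other splits and the test of array scaling were chosen earlier.

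Of the 28 named genes called for the difference between the TRAIL responses, 21 were flagged. They are the 10 highest, the 10 lowest and NFKBIA. The rest are members of the gene lists and are given above. The 3D response was below the 2D response for CXCL2 (-7.23), CXCL8 (-5.60), CXCL3 (-5.29), TNFAIP3 (-4.66), ATF3 (-4.43), GEM (-4.13), IRF1 (-4.12), FOS (-3.23), IL1A (-3.20), PLAU (-3.14) and NFKBIA (-1.94), on the log2 scale. Those of CXCL2, CXCL8, CXCL3, ATF3, GEM and IL1A rest on 2D control means below the array median. It was above the 2D response for EXOC5 (4.60), MBTPS2 (3.61), PCM1 (2.86), ERBIN (2.45), RMI1 (2.25), SSX2IP (2.15), SMC3 (2.09), PKN2 (2.06), EPRS1 (1.96) and WASHC4 (1.82). For EXOC5, CXCL8 and CXCL3 both 3D groups lay below the array median, so their 3D signal was not shown to lie above background. MBTPS2, PCM1, RMI1, SMC3 and PKN2 had 3D control means below it, and the 2D TRAIL mean of MBTPS2 also lay below it. With such means set to the median, the differences of EXOC5, MBTPS2, PCM1 and SMC3 were 1.18, 1.72, 2.01 and 1.85. Those of RMI1 and PKN2 hardly changed (2.19 and 2.05).

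The first pattern is that NF-kB target genes rose with TRAIL in 2D, by a mean of 2.98, and were not called as a list in 3D (0.08). An exchange of 3D control 1 and 3D TRAIL 1 is argued against as the cause for this list. With their labels exchanged its mean 3D change was 0.46 (SD between genes 0.67; adjusted p = 0.251), with 1 of its 23 genes called, against 0 with the labels as given. The count of 0 genes in 3D is another matter, since the exchanged labels call 657, and there an exchange stays open. RNA quality of 2D TRAIL 2 and 3 is argued against as the whole cause, since with the 18S signal as a covariate the mean 2D change of the list was 2.47 (adjusted p = 1.96e-14, with 2.74e-32 to 0.00624 over the alternatives). 3D controls that already stand fully at the TRAIL level are argued against for the list mean, which lay below 2D TRAIL there (3D control minus 2D TRAIL -2.12, SD between arrays at most 0.66). A higher level in 3D control as part of the cause is not excluded, and genes differed in this. NFKBIA read 12.7 to 13.15 in 3D control, against 10.98 to 11.9 in 2D control and 13.61 to 13.7 in 2D TRAIL. CXCL8 read 4.11 to 5.44 in 3D control, against 9.02 to 10.46 in 2D TRAIL.

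A biological explanation, that culture in basement membrane may blunt the NF-kB response to TRAIL, stays open as a hypothesis found on these data. The 3D cultures were grown for 12 days, and no time is given for the monolayers. Cell cycle genes also differed between the control cultures. The matrix, the time in culture and the state of growth can therefore not be told apart. The splits do not exclude chance for the difference: of 100 relabellings within each kind of culture, 5 called at least the real 54 genes, the highest other calling 841, and 12 called at least the real 5 lists, the highest other calling 11. These counts say little, because 9 of the 100, the real one included, keep the 2D labels and with them the 2D response. The 91 that change the 2D labels called at most 18 genes, and 4 of them called at least 5 lists. The relabellings that called 841 and 197 genes both part the 3D arrays as the second pattern does, and the other 6 that keep the 2D labels called 27 to 71. Whether the caspase inhibitors were also on the vehicle cultures is not stated, so inhibitor and TRAIL effects could not be separated.

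The second pattern is a structure of the 3D samples: 3D control 1, TRAIL 2 and TRAIL 3 against 3D control 2, control 3 and TRAIL 1 gave 657 genes (397 higher, 260 lower), where the real split gave 0. Array scaling is argued against, since 559 genes were called after quantile normalization. RNA quality stays open. Of 3 3'/5' ratios 1 separated the arrays, that of GAPDH (-0.04 to 0.037 against 0.133 to 0.322), which leaves 3'/5' RNA quality undecided. The rRNA in the labelled RNA went with the split, as 5 of 6 rRNA control probe sets separated the arrays, 18S rRNA at 6.27 to 6.78 against 3.52 to 5.40. With the 18S signal as a covariate the split called 34 genes, 30 of them among the 657, though that signal runs along the split. An exchange of 3D control 1 and 3D TRAIL 1 cannot be told apart from these. This split called 5 of the 106 genes raised in 2D higher, a share close to that of all genes (397 of 7828). It is not known that TRAIL raises the 106 genes in 3D, so this count does not decide. If the 2 arrays were exchanged, a TRAIL response in 3D of other genes might be hidden by the labels. No biological explanation was tested.

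The third pattern is the 18S rRNA control signal, a control measure outside the 5 contrasts as planned, at 11.53 on 2D TRAIL 2 and 11.45 on 2D TRAIL 3. It is consistent with RNA quality, since the lower actin 3'/5' ratio of these arrays exceeded the highest of the other 10 by 0.32 and the GAPDH ratio by 0.27. 2D TRAIL 1 lacks the signal, and its NF-kB list rose by 2.71 over the 2D controls, against 3.08 and 3.17 on the other 2. A biological cause in TRAIL-treated monolayers, such as dying cells, was not tested.

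The 6 arrays of a comparison of 2 groups allow 10 splits, too few for a share under 0.05. For TRAIL in 2D, 1 of 10 splits gave at least the real 125 genes (highest other 1) and 1 of 10 the real 10 lists (highest other 5). For TRAIL in 3D, 10 of 10 gave at least the real 0 genes (highest other 657) and 2 of 10 the real 2 lists (highest other 2). For 3D against 2D in control, 1 of 10 gave 2013 genes (highest other 0) and 1 of 10 gave 7 lists (highest other 5). For 3D against 2D with TRAIL, 1 of 10 gave 1230 genes (highest other 0) and 1 of 10 gave 7 lists (highest other 5).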

How the results depend on the processing

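The covariates, the fits without pairs of arrays, the offset or floor before log2 and the lists with each array left out were chosen only after the data were seen. The cause of a change below was not tested, except where fewer arrays or an added fold threshold bring it by construction. The count of 125 genes for TRAIL in 2D was 83 without the trend, 342 with array weights, 249 from the compared arrays alone, 55 and 51 with the actin or 18S covariate (53 and 38 of them among the 125), and 36 without 2D TRAIL 2 and 3. The count of 0 for TRAIL in 3D was 1 without the dim filter, with the mean of probe sets or without the trend, 2 with each probe set, 13 with array weights and 269 without 3D control 1 and TRAIL 1. Those arrays were picked from the split that calls most genes, so the last count is circular. For the difference, 54 genes became 33 without the filter, 23 without the trend, 200 with array weights, 34 with a replicate block, 24 with the actin covariate, 0 without 2D TRAIL 2 and 3 and 450 without 3D control 1 and TRAIL 1. Changes of at least 2-fold were 1238 in control and 745 with TRAIL between the cultures; the latter contrast gave 395 and 284 genes with the actin and 18S covariates and 228 without 2D TRAIL 2 and 3. The correlation of the responses was -0.03 with the stricter filter and -0.02 with each probe set. Called lists were 4 with an estimated correlation and 6 with the 18S covariate in 2D; 1 without the filter or with quantile normalization and 0 with an estimated correlation or fry in 3D; and 2 with an estimated correlation and 3 without 3D control 1 and TRAIL 1 for the difference. Between the cultures they were 1 with an estimated correlation and 12 with fry in control, and 2 and 16 with TRAIL. The ribosomal list in 2D reversed with quantile normalization, to a mean of 0 (adjusted p = 0.947).

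Leaving out 1 array at a time gave 54 to 116 genes in 2D, 0 to 6 in 3D, 25 to 105 for the difference, 1337 to 2051 and 646 to 1063 for the cultures in control and with TRAIL, and r of -0.03 to 0.081. The lists numbered 9 to 10, 1 to 3, 4 to 6, 6 to 7 and 7 to 7. Of the results for named genes with 1 array left out, 2701 kept direction and side of the threshold, 370 lost the call and 7 gained it; of those for lists, 1023 kept it, 14 lost it and 7 gained it. Replicates of the same number did not behave as pairs: their deviations correlated at -0.34 to 0.09, with 0 of 18 above 0.1. The 4135 genes that lay above the array median on fewer than 3 arrays were not tested.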

Other observations

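The test of NF-kB genes in the 3D controls was chosen only after the result was seen.

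Some stress, metabolic and adhesion genes also differed between 3D and 2D control cultures, where 25.7% of all genes were called. Their lists had members that went both ways and were not called by camera. Fry called the glycolysis and hypoxia list higher (adjusted p = 0.0169). Of 11 heat shock genes 3 were higher and 2 lower, or 3 and 4 adjusted over the list alone: HSPB1 was 3.28-fold higher (1.72 ± 0.13, adjusted p = 1.85e-07) and DNAJB1 2.48-fold, while the chaperone genes HSP90AA1 and HSPH1 were 3.65-fold and 3.43-fold lower. Of 20 glycolysis and hypoxia genes 7 were higher and 1 lower, with ADM 5.96-fold, ALDOA 2.78-fold and the glucose transporter gene SLC2A1 2.74-fold higher, and PFKFB3 2.45-fold lower. Of 21 stress response genes 4 were higher and 5 lower, among them SLC3A2 (2.78-fold higher) and HSP90B1 (6.32-fold lower).

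Among 18 hemidesmosome and basement membrane genes 3 were higher and 3 lower. The integrin gene ITGA6 was 6.47-fold lower (-2.69 ± 0.31, adjusted p = 1.16e-05), DST 4.56-fold lower and HSPG2, the perlecan gene, 2.78-fold higher; ITGA6 and HSPG2 kept these signs with TRAIL (-1.18 and 1.26). Of 22 junction genes 7 were higher and 5 lower, with DSG2 3.5-fold and DSC3 3.03-fold lower and PRKCZ 2.64-fold and PKP1 2.41-fold higher. Of 17 matrix remodelling genes 6 were higher and 3 lower, with PLAU 4.3-fold higher and FN1 4.28-fold and TIMP1 2.8-fold lower. The fibroblast marker FBLN1 (3.57-fold) and the adipocyte marker FABP4 (at least 7.38-fold) were each the 1 called gene of 3 on lists that camera did not call (adjusted p = 0.947 and 0.544), though fry called the adipocyte list (0.0106).

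A hypothesis is that basement membrane culture may raise NF-kB target genes without TRAIL, though the matrix cannot be told apart from time in culture. The list was higher in 3D control by a mean of 0.87, which passed with a preset correlation and not with an estimated one (adjusted p = 0.547), and the per-array means ranged from -1.04 to 0.26 in 3D control against -1.36 to -0.97 in 2D control, so this stays open.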
